A study of Mus musculus with 8 samples.

How the data were processed

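Livers of mice aged 8 to 9 weeks were collected 48 hours after partial hepatectomy, per the labels' protocols. The labels name 3 control livers, genotype URI(+/+)Hep, and 5 livers of genotype URI(+/D)Hep, in which URI was deleted in hepatocytes with a tamoxifen-inducible Cre driven by serum albumin sequences. The notation +/D sets a wild-type allele, +, beside a D allele. Mice received tamoxifen for 1 week, and the controls were wild-type littermates, per the labels. Each library came from total RNA and was made with oligo-dT priming, so that reads come from the 3′ ends of transcripts. A random second-strand primer carried a unique molecular identifier of 6 nt, and the libraries kept the sense strand, per the labels' protocols.

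The submitters' processing notes name bcl2fastq, featureCounts, DESeq2 and the build GRCm39, without versions or order. The aligner, the gene annotation and the treatment of the molecular identifiers are not given in the sources used here, so it is open whether a value counts reads or molecules. The deposited table, made by the authors, holds normalized signal for 19055 gene symbols in 8 libraries, that is, read counts divided by a size factor for each library. Dividing each library by its smallest value above 0 gave whole numbers, within a tolerance of 1e-06, for 100% of the values. The smallest total over the 8 libraries was 10 reads, so rows with fewer reads were not in the table. The recovered depth ranged from 3838674 to 4800694 reads per library. A count of 3 reads corresponds to 2.65 to 3.60 normalized reads, and values near that level are uncertain, as in some libraries for Mup7, Sult3a1, Kif4, Gzma and Pax5. The available reference annotation is of another build, so no coordinates are given. Of the symbols, 18871 matched its name tables, which were used for names, transcript length and GC content only.

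Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, using its mean-variance trend and Benjamini-Hochberg adjustment. Genes with a value of at least 10 in at least 3 libraries were tested, which left 13704. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and an adjusted p under 0.05 was called. Normalized values are given as mean ± SD over 3 control libraries and 5 libraries labelled URI(+/D)Hep unless stated otherwise. Of 46 gene lists fixed before the data were examined, 45 with at least 5 measured members were tested with camera at a preset correlation of 0.01. The remaining list, adipose and pancreas carry-over, had fewer measured members and was tested only without the filter, where it was not called (median log2 fold change 0.94, camera adjusted p = 0.228). The lists were also tested with camera using an estimated correlation, and with fry. The fry p asks whether the genes of a list move, on balance, one way, without comparing them with other genes. The median of each list was also compared with its values in all 56 splits of the 8 libraries into 3 and 5, a two-sided exact permutation test chosen after the list results were seen.

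The genes named were chosen by a rule fixed before the data were examined. They are 10 genes picked by name, up to 10 called genes per direction with a mean of at least 20 in the higher group and ranges that did not overlap, filled to 5 per direction by smallest p, and up to 3 called or otherwise 2 members per list by smallest p. Genes that did not pass the threshold are given as values only. The members of the cholesterol synthesis list that the rule picks are not reported here. Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty fall outside the rule and were singled out after their values were seen.

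Alternatives fixed before the data were examined were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, TMM recentring, quantile normalization, limma without the trend, array quality weights, a block for the replicate number, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. No control has replicate number 4 or 5, so the block leaves URI(+/D)Hep 4 and 5 without a part in the group difference. The iterations for the array quality weights stopped before reaching their tolerance. The smallest value above 0 in the library of URI(+/D)Hep replicate 5 was close to 1, which leaves less certainty that it stands for a single read, and the count tests were also run on the other 7 libraries. Other settings added after seeing the data were a covariate for the share of Y-linked reads, a fit of the 5 libraries with both Xist and Y-linked reads, where control 3 is the 1 control and is assumed to vary like the other group, and a fit without the 2 libraries lowest on the first principal component.

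The limma and camera steps were tested on simulated data built from the means and depths of these libraries. Of 13499 simulated genes tested, 64 had been changed 4-fold, of which 81.2% were recovered. Of 66 genes changed 2-fold, 25.8% were recovered, and of 65 changed 1.5-fold, 4.62% were recovered. Among 79 calls, 7 were false. Each gene was simulated independently, without the variation that genes share between these libraries, so these rates may not hold for the real data. The labels do not say how many animals each library holds, and p-values measure the spread between these libraries. Figures were drawn with matplotlib 3.10.9.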

Results

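Gene expression was measured in 8 mouse liver libraries 48 hours after partial hepatectomy, when remaining hepatocytes divide to restore liver mass. The comparison set 3 livers labelled URI(+/+)Hep against 5 livers labelled URI(+/D)Hep. It asks how deletion of URI in hepatocytes, a prefoldin-like protein encoded by Uri1, bears on the regenerating liver, in a genotype whose notation keeps a wild-type allele. Depth ranged from 3838674 to 4337966 reads in the controls and from 4294494 to 4800694 reads in the libraries labelled URI(+/D)Hep. Between 17939 and 18648 genes had at least 1 read in a library.

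Uri1 itself did not differ between the groups. It reached 468, 374 and 310 normalized reads in controls 1, 2 and 3, and 328, 398, 437, 354 and 401 in the livers labelled URI(+/D)Hep 1 to 5. The means were 384 ± 79.3 and 384 ± 42.7, with a log2 fold change of 0.01 (SE 0.15, 95% interval -0.33 to 0.35). The two-sided exact permutation p was 0.982, where 56 splits allow a p as small as 0.0179, and limma gave an adjusted p of 0.975. The 95% interval corresponds to 0.80- to 1.28-fold of the control, so a larger fall of the counted Uri1 reads lies outside it. A 3′ tag outside the deleted part of a gene need not show the deletion, and the deleted part is not given in the sources used here. The groups are therefore named by their labels throughout, and every direction rests on those labels.

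Transcripts specific to a sex differed between and within the groups. Xist, the RNA that coats the inactive X chromosome, stood at 9.59 and 2.95 normalized reads in controls 1 and 2, at 1298 in control 3 and between 1217 and 2357 in the livers labelled URI(+/D)Hep. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 1558 and 1312 in controls 1 and 2, to 569 in control 3 and to 3.54 in URI(+/D)Hep 1. In URI(+/D)Hep 2 to 5 the sum lay between 786 and 1002. Control 3 and URI(+/D)Hep 2 to 5 thus held both kinds of transcript, and no library labelled URI(+/D)Hep resembled controls 1 and 2 in both measures.

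**Figure D1:**
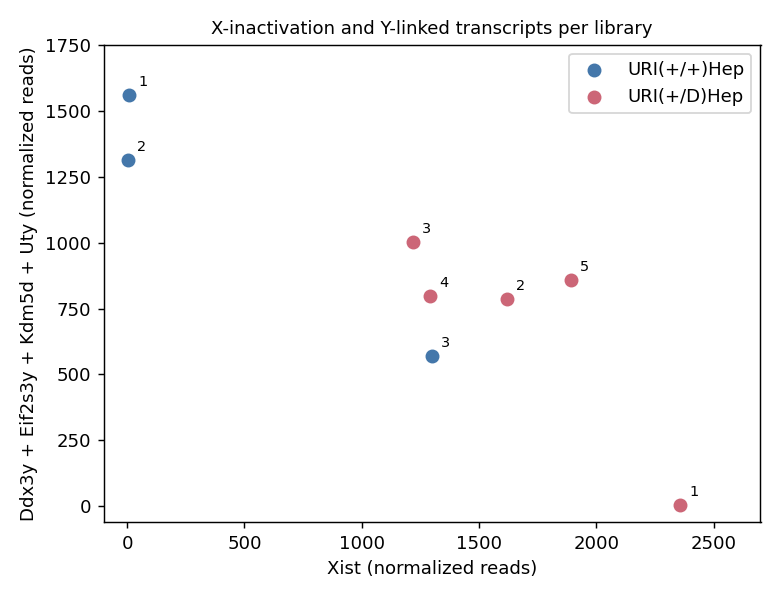
Xist (horizontal axis, normalized reads) against the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (vertical axis, normalized reads), with 1 point per library, numbered by replicate and coloured by group. Controls 1 and 2 lie at 9.59 and 2.95 for Xist, and URI(+/D)Hep 1 at 3.54 for the Y-linked sum, while the other 5 libraries hold both.

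Tuft1 and Rps4l fell in the livers labelled URI(+/D)Hep. Tuft1, which encodes tuftelin, went from 318 ± 68.5 to 93.1 ± 15.2 normalized reads, a log2 fold change of -1.76 (SE 0.18, limma adjusted p = 0.0333). Rps4l, a paralogue of the ribosomal protein gene Rps4x, went from 406 ± 26.9 to 173 ± 21.0, a log2 fold change of -1.23 (SE 0.13, limma adjusted p = 0.0333). All 5 libraries labelled URI(+/D)Hep lay below all 3 controls for both genes. Reads of Rps4l may be shared with related copies, so its level is uncertain. These were the 2 genes called lower of 13704 tested, and 0 were called higher by limma. At an unadjusted p under 0.05, limma counted 1144 higher and 1278 lower genes, where chance gives 685 in all. The ranges of the groups did not overlap for 1841 genes (13.4%, against 3.57% by chance). Of the 56 splits of the 8 libraries, 4 gave at least as many calls. The unadjusted p-values and the ranges were not counted in the other splits, so their excess over chance is not shown to follow the labels. Both calls were lost without any 1 library other than control 3, while over 24 alternatives the log2 fold changes stayed between -1.92 and -1.37 for Tuft1 and between -1.31 and -1.16 for Rps4l. Without control 3 there were 11 higher and 23 lower genes. That fit sets controls 1 and 2, with Xist at 9.59 and 2.95, against libraries that all hold Xist. Xist led its calls, which also held Sult3a1, Cyp2b13 and Mup7. Sex composition and genotype can therefore not be told apart without control 3, also for the list medians given below. On recovered reads edgeR called 0 higher and 3 lower genes, and DESeq2 called 236 higher and 376 lower, leaving 4533 of the 13704 genes without an adjusted p.

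The genes next in order did not pass the threshold in limma. Psat1, a serine synthesis enzyme, stood at 162 ± 40.03 against 49.2 ± 8.04 (log2 fold change -1.68, SE 0.20, adjusted p = 0.0608). Ldhd, which oxidizes D-lactate, had a log2 fold change of -0.92 (SE 0.13, adjusted p = 0.108), and Rps19, of the small ribosomal subunit, one of -0.62 (SE 0.10, adjusted p = 0.108). Cdk8, the kinase of the Mediator complex, stood at 320 ± 6.73 against 562 ± 47.3 (log2 fold change 0.81, SE 0.10, adjusted p = 0.0608). Ksr2, Rapgef4 and Ldlrad4 had log2 fold changes of 1.41, 0.69 and 0.70. Kdm6a, an X-linked gene that escapes X inactivation, had one of 0.64. In control 3, with Xist at 1298, it stood at 186 normalized reads, near controls 1 and 2 at 176 and 202, against 275 to 307 in the libraries labelled URI(+/D)Hep. The ranges of the groups did not overlap for any of these 8 genes.

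**Figure D2:**
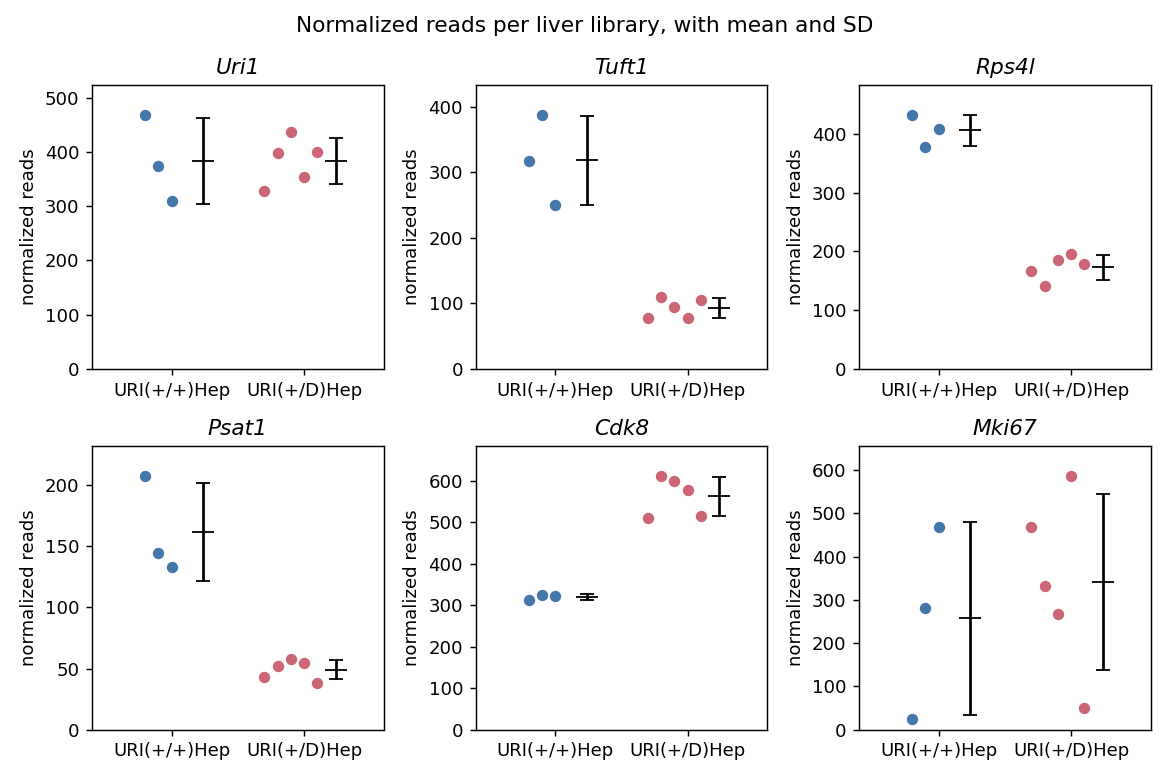
Normalized reads (vertical axes, linear and from 0) of Uri1, Tuft1, Rps4l, Psat1, Cdk8 and Mki67, with 1 point per library, and the mean with its SD as a bar beside the points. Tuft1 ranges from 250 to 387 in controls and from 77.7 to 110 in libraries labelled URI(+/D)Hep, while the Uri1 ranges overlap.

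Genes of protein synthesis were lower as groups in the livers labelled URI(+/D)Hep. Of 71 measured cytosolic ribosomal protein genes, 63 had a negative log2 fold change, with a median of -0.38 (camera adjusted p = 2.25e-14). Over all genes tested 0 of them fell, and adjusted over the list alone 30 fell, while DESeq2 on recovered reads called 23 lower over the genes it adjusted. This call was lost with another correlation: adjusted p = 0.564 with an estimated correlation. The median was -0.28 without control 1, and the list mean was 0.47 in control 1 against 0.04 and 0.13 in controls 2 and 3. Rps19 stood at 1333 ± 129 against 863 ± 39.0 normalized reads and Rps15a at 1569 ± 157 against 1000 ± 94.1. The share of all reads in ribosomal protein genes was 1.14 to 1.25% in controls and 0.879 to 0.964% in libraries labelled URI(+/D)Hep. Ribosome biogenesis genes had a median of -0.20, with 35 of 41 negative, 0 called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 5.36e-05, and adjusted p = 0.564 with an estimated correlation). The median was -0.13 without control 1 and -0.32 without control 3, and against control 3 alone the call was lost, with a median of -0.14. The list mean was 0.30 in control 1 against 0.08 and 0.04 in controls 2 and 3. DESeq2 called 6 of the genes lower. Examples from the list were Nop16, at 364 ± 48.4 against 239 ± 23.7, and Mybbp1a, at 317 ± 55.8 against 203 ± 23.2.

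The unfolded protein and integrated stress response list was also lower, with a median log2 fold change of -0.31 and 24 of 29 genes negative (camera adjusted p = 0.000898, and adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 3 genes fell and 1 rose, against 0 over all genes, while DESeq2 called 4 lower and 1 higher over the genes it adjusted. Trib3, a pseudokinase induced by stress, stood at 98.2 ± 18.3 against 37.5 ± 10.98 normalized reads. Atf4, the transcription factor of that response, stood at 1566 ± 230 against 1005 ± 182. The acute phase list had a median of -0.55 with 25 of 28 genes negative (camera adjusted p = 5.17e-06, and adjusted p = 0.564 with an estimated correlation), and 3 of its genes fell adjusted over the list alone, while DESeq2 called 8 lower over the genes it adjusted. The median was -0.36 without control 1, -0.78 without control 3 and -0.33 with the Y-linked share as a covariate, and the list mean of control 3, -0.18, lay within the range of the libraries labelled URI(+/D)Hep, -0.43 to 0.07. Against control 3 alone the acute phase call was lost. Examples from this list were Apcs, serum amyloid P, at 3062 ± 312 against 1452 ± 413, and Lbp, the lipopolysaccharide binding protein, at 824 ± 43.5 against 591 ± 62.5.

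Lists of genes with a known sex bias in mouse liver also differed between the groups. Female-biased genes had a median log2 fold change of 1.35, with 19 of 21 positive (camera adjusted p = 5.36e-05, and adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone 3 of them rose. Sult3a1 stood at 9.53 ± 8.76 against 69.7 ± 26.9 normalized reads and Cux2 at 166 ± 54.8 against 379 ± 105. Male-biased genes had a median of -0.84, with 10 of 15 negative (camera adjusted p = 0.0121, and adjusted p = 0.564 with an estimated correlation), and 2 fell adjusted over the list alone. Mup7 stood at 145, 164 and 15.02 in controls 1 to 3 and at 8.43 or less in the other libraries. With the Y-linked share as a covariate the medians were 0.58 and -0.43. Without control 1 the call of the female-biased list was lost, with a median of 0.46, and without control 3 the median was 2.24. The call of the male-biased list was lost without control 2, with a median of -0.73, and among genes with a mean of at least 50 normalized reads, with a median of 0.04. Both calls were also lost in the fit with control 3 as the 1 control.

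Lists of metabolic and hepatocyte genes went in both directions. Pericentral genes, expressed around the central vein, had a median log2 fold change of 0.49 with 23 of 28 positive (camera adjusted p = 0.00764, and adjusted p = 0.858 with an estimated correlation). Their examples were Aldh3a2, at 449 ± 125 against 761 ± 161, and Rnf43, at 164 ± 84.8 against 308 ± 88.1. The call was lost without control 1, with a median of 0.07, without URI(+/D)Hep 1, without both control 1 and URI(+/D)Hep 5, and with the Y-linked share as a covariate, with a median of -0.02. The median was 0.76 without control 3. Cholesterol synthesis genes had a median of -0.42 with 23 of 24 negative (camera adjusted p = 0.00266, and adjusted p = 0.782 with an estimated correlation), and the call was lost without control 1, with a median of -0.31, and with the Y-linked share as a covariate, with one of -0.06. Hepatocyte secreted products had a median of -0.21 with 24 of 28 negative (camera adjusted p = 0.0121, and adjusted p = 0.782 with an estimated correlation). The call was lost without control 1, with a median of -0.07, without both control 1 and URI(+/D)Hep 5 (-0.08), with quantile normalization (-0.07), with array weights (-0.17) and with the Y-linked share as a covariate (-0.23). The list mean was 0.38 in control 1 against 0.03 and -0.06 in controls 2 and 3. Among them Fetub stood at 1336 ± 105 against 967 ± 108 and Apob, the main protein of very low density lipoprotein, at 2344 ± 253 against 3647 ± 683. Adjusted over each list alone, 0 pericentral and 0 cholesterol synthesis genes passed, and 1 secreted product rose and 1 fell.

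Markers of other liver cells were included because whole tissue was sequenced. Neutrophil markers had a median log2 fold change of -0.92 with 9 of 9 negative (camera adjusted p = 0.00141, and adjusted p = 0.73 with an estimated correlation). The call was lost without control 1, with a median of -0.68, and with the Y-linked share as a covariate, with one of -0.34, and control 3, at a list mean of -0.55, lay within the range of the libraries labelled URI(+/D)Hep, -1.04 to 0.26. Monocyte markers had a median of -0.61 (camera adjusted p = 0.0369, and adjusted p = 0.782 with an estimated correlation). The call was lost without control 1 (median -0.67), without control 2 (-0.37), without URI(+/D)Hep 1 (-0.43), without both control 1 and URI(+/D)Hep 5 (-0.73), with the Y-linked share as a covariate (-0.13) and among genes with a mean of at least 50 normalized reads (-0.36). The median was -1.49 without control 3. Mmp9 stood at 70.6 ± 24.9 against 33.7 ± 4.96 and Ccr2, a monocyte chemokine receptor, at 113 ± 48.1 against 45.1 ± 16.7. Stellate cell and matrix genes had a median of -0.21 (camera adjusted p = 0.0477, and adjusted p = 0.782 with an estimated correlation), including Mmp14 at 1039 ± 127 against 770 ± 37.0. This call was lost in 10 of 20 settings, with medians of -0.10 without control 1, -0.11 without control 2 and -0.05 with the Y-linked share as a covariate, and the median was -0.43 without control 3. Endothelial markers had a median of 0.27 (camera adjusted p = 0.0121, and adjusted p = 0.564 with an estimated correlation), including Tek at 95.7 ± 8.86 against 157 ± 17.9 and F8 at 189 ± 39.4 against 335 ± 65.7. Without control 1 the call was lost, with a median of 0.22, and without control 3 the median was 0.15. This call was also lost in the fit with control 3 as the 1 control. B and plasma cell markers had a median of 1.29 over 7 genes (camera adjusted p = 0.0124, and adjusted p = 0.564 with an estimated correlation), with Ebf1 at 24.03 ± 16.3 against 59.4 ± 13.5. The call was lost without control 1 (median 0.73), without both control 1 and URI(+/D)Hep 5 (0.59), without a filter on low values (0.49) and with the Y-linked share as a covariate (0.90), and with a pseudocount of 8 the median was 0.77. The list mean of control 1 was -1.75 against -0.41 and -0.12 in controls 2 and 3. Adjusted over each list alone, 2 neutrophil and 2 stellate genes fell, 2 endothelial genes rose, and 0 monocyte and 0 B cell genes passed.

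In all, 14 lists were called with the preset correlation, 4 higher and 10 lower. Some of these lists share genes, so the calls are not all separate results. Fga, Fgb, Fgg, Itih3 and Itih4 are in the acute phase and secreted product lists, and Lcn2 is in the acute phase and neutrophil lists. With an estimated correlation 0 were called, the smallest adjusted p being 0.564, and fry called 0. With the Y-linked share as a covariate 7 of these 14 were called in the same direction, and without control 1 the number was 5. Of the 56 splits of the 8 libraries into 3 and 5, 27 gave at least as many called lists. Against control 3 alone, 1 library, the pericentral list was called lower (median -0.42, camera adjusted p = 0.00672), and the medians of the female-biased (-0.30), neutrophil (0.22), monocyte (0.49), cholesterol synthesis (0.15) and stellate (0.15) lists had the other sign without a call. The calls of the male-biased, endothelial, B cell, secreted product, ribosome biogenesis and acute phase lists were also lost against control 3 alone. The 5 lists still called without control 1 were the ribosomal protein, ribosome biogenesis, stress response, acute phase and male-biased lists.

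**Figure D3:**
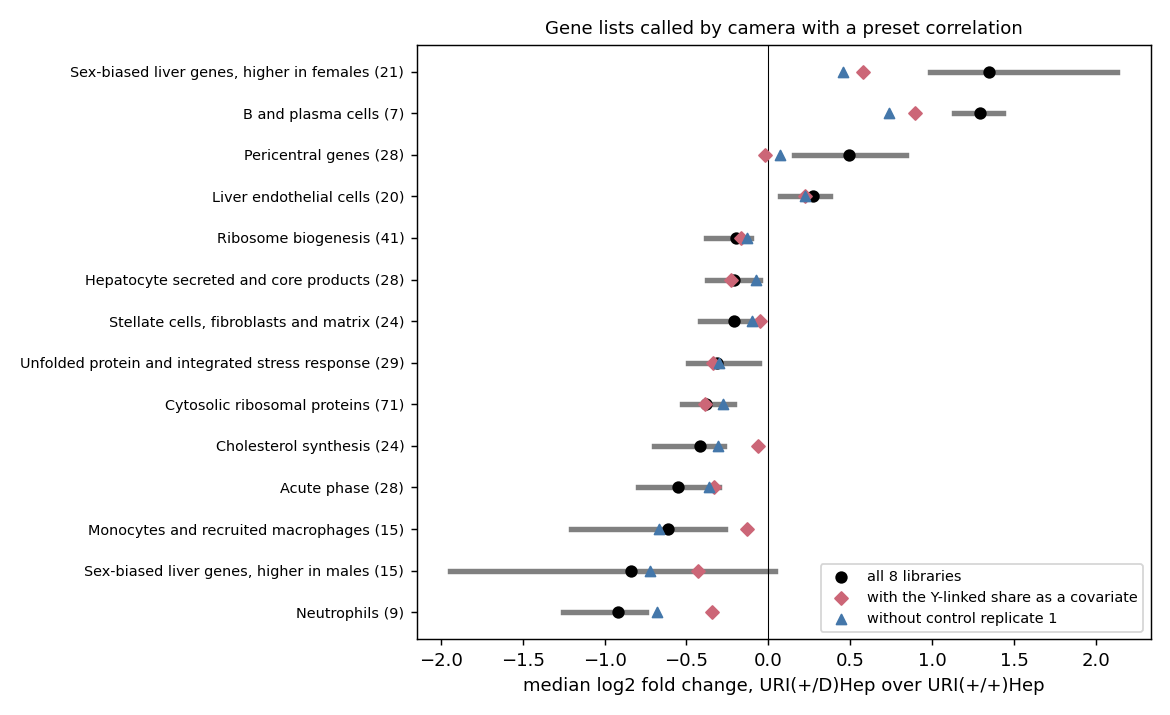
Median log2 fold change (horizontal axis) of the 14 gene lists called by camera with the preset correlation, with the number of measured genes in parentheses. Black points stand for all 8 libraries with grey bars for the quartiles of the genes, diamonds for the fit with the Y-linked share, and triangles for the fit without control 1. The ribosomal protein median is -0.38, -0.39 and -0.28 in the 3 fits, and the pericentral median is 0.49, -0.02 and 0.07.

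Cell cycle genes varied widely within both groups. Mki67, a marker of dividing cells, stood at 23.99 in control 1, 282 in control 2 and 468 in control 3. In the livers labelled URI(+/D)Hep it stood at 469, 333, 268, 586 and 49.5. Its log2 fold change was 0.82 (SE 1.03, limma adjusted p = 0.72). The G2 and mitosis list had a median of 0.47 (camera adjusted p = 0.13, and adjusted p = 0.968 with an estimated correlation, the correlation itself being 0.955). It was called lower without control 1 (median -0.58, camera adjusted p = 0.00361) and with the Y-linked share as a covariate (-0.50, 0.0205), and against control 3 alone (-1.16, 4.68e-06). It was called higher without control 2 (0.84, 0.00946), without control 3 (1.16, 3.88e-05), without URI(+/D)Hep 5 (1.01, 9.89e-06) and with a block for the replicate number (0.93, 8.72e-05). The block takes out URI(+/D)Hep 4 and 5, whose replicate numbers no control shares, so it also leaves out URI(+/D)Hep 5. The S phase list had a median of 0.14 (camera adjusted p = 0.315, and adjusted p = 0.968 with an estimated correlation). It was called lower with the Y-linked share as a covariate (-0.43, 0.0059) and against control 3 alone (-0.74, 0.000278), and higher without control 3 (0.56, 0.00266), without URI(+/D)Hep 5 (0.47, 0.000397) and with the block (0.41, 0.00628). Control 1 and URI(+/D)Hep 5 also lay lowest on the first principal component, at -78.2 and -35.2, which held 48.8% of the variance. Ccnd1, the G1 cyclin D1, stood at 2670 ± 1302 against 3880 ± 795 (limma adjusted p = 0.33).

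Genes linked to URI by name or by earlier study did not pass the threshold. The URI prefoldin-like and R2TP complex list had a median log2 fold change of -0.05 (camera adjusted p = 0.631) and the RNA polymerase II subunits one of -0.24 (camera adjusted p = 0.106). Of the 12 polymerase genes 9 were negative, and the median was -0.14 without control 1. By the exact permutation test of the polymerase median, p was 0.0357 (0.201 adjusted over the lists). Polr2e, a subunit in both lists, stood at 139 ± 12.8 against 99.1 ± 12.2 normalized reads. Glul, the glutamine synthetase gene, stood at 1303 ± 817 against 1884 ± 446 (log2 fold change 0.74, SE 0.41), Yap1 at 516 ± 106 against 443 ± 15.5 and Hif1a at 124 ± 63.7 against 149 ± 30.5. Alb stood at 8996 ± 2042 against 7916 ± 1903 and Afp at 75.1 ± 51.1 against 27.9 ± 16.5. Myc did not pass the filter on low values, with 22.8 in control 1 and between 4.68 and 8.84 in the other 7 libraries, and Wnt3 was not analysed here.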

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

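The count of splits for gene calls and the tests on sex composition, control 1, and transcript length were set before their results were seen, and the permutation test of each list was chosen afterwards. Of 154 measures tested for a library far from the others among the 5 labelled URI(+/D)Hep, 7 stood out. Chance gives about 1 in 20, so the count is no more than chance would give if the measures were independent. They come from the same libraries and are not, and the count does not make each of them a chance result. The gap to the nearest library as a share of the range was 0.784 for the Y-linked sum, where URI(+/D)Hep 1 had 3.54 normalized reads against 786 to 1002 in the others of its group. It was 0.819 for the mean of the cholangiocyte markers, highest in URI(+/D)Hep 5 at 1.56 against -0.45 to -0.09. It was 0.778 for the RNA polymerase II subunits and 0.76 for Ndrg1, both highest in URI(+/D)Hep 1. It was 0.711 for Ldhd, lowest in URI(+/D)Hep 5, 0.757 for Rxra, lowest in URI(+/D)Hep 2, and 0.736 for Gzma, highest in URI(+/D)Hep 5.

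Chance could not be excluded for the counts of calls. Of 56 splits of the 8 libraries into 3 and 5, 4 gave at least the 2 genes of the labelled groups, and the highest other split gave 120 genes. That split set control 3 with URI(+/D)Hep 1 and 4, the libraries at 36.1, 41.1 and 40.002 on the first principal component, which points to a structure of the samples other than the labels. For the gene lists, 27 of 56 splits gave at least the 14 called lists, and the highest other split gave 24. By the exact permutation test of each list's median, 5 lists had the smallest p that 56 splits allow, 0.0179, namely ribosomal proteins, ribosome biogenesis, male-biased genes, endothelial markers, and G1 and growth factor response. For the other called lists this permutation p was 0.0357 for acute phase and B cell, 0.0536 for stress response, and 0.107 for neutrophil and secreted product lists. It was 0.179 for pericentral, 0.196 for female-biased, 0.214 for monocyte, 0.232 for stellate and 0.321 for cholesterol synthesis lists. The smallest adjusted p over the 45 lists was 0.161, but 17 lists at a p of 0.0179, or more at a larger one, would be needed for any to pass, so this says little of single lists.

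Female-biased genes were higher and male-biased genes lower in livers labelled URI(+/D)Hep, with a difference of medians of 2.19. With the Y-linked share as a covariate 46.1% of that difference was left, so that the sex composition of the libraries may account for a large part of it. The lists did not follow the sex-linked transcripts in each library, however. Control 3 had a lower Y-linked sum than URI(+/D)Hep 2 to 5 and yet a higher mean of male-biased genes (0.30 against -0.69 to -0.17), and URI(+/D)Hep 5, with Xist at 1891, had a mean of female-biased genes of -0.24. Without control 1, 53.8% was left, which lay between the bounds set beforehand, and that library's part stays open. Libraries with both Xist and Y-linked reads may hold RNA of animals of both sexes, by pooling or by carry-over, or material may have been exchanged, and the tables do not separate these. By Spearman correlation over genes, control 3 stood nearer to URI(+/D)Hep 1 and 4 (0.977 and 0.979) than to controls 1 and 2 (0.907 and 0.970), but farther from URI(+/D)Hep 2, 3 and 5 (0.966, 0.963 and 0.928) than from control 2. Both lists were still called with the covariate (camera adjusted p = 0.0212 for female-biased and 0.0059 for male-biased genes, with the preset correlation), so a part tied to the genotype stays open. In the fit with control 3 as the 1 control, both calls were lost and the female-biased median turned negative. With all libraries and no covariate both calls were lost, at adjusted p = 0.65 and adjusted p = 0.564 with an estimated correlation, and the labels do not give the sex of the animals.

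Cytosolic ribosomal protein genes were lower in livers labelled URI(+/D)Hep. The Y-linked share as a covariate left 101% of their median log2 fold change, which argues against a cause that follows that share. Xist, which parts the libraries in another way, was not used as a covariate, so sex composition as a whole stays open. A fit on transcript length and GC content left 79.1% of the median, which argues against these as the whole cause. Without control 1, 71.9% was left, between the bounds set beforehand, so the part of that library stays open, although the list was still called there (camera adjusted p = 6.56e-07, and 4.68e-06 at most over 20 settings, all with the preset correlation). With all libraries this call was lost, at adjusted p = 0.564 with an estimated correlation. Lower ribosomal protein expression with the genotype is a candidate explanation, but the share of mitochondrial reads also separated the groups, at 1.76 to 1.91% and 2.22 to 2.65%. This share includes the ribosomal RNAs mt-Rnr1, at 7037 against 14956 normalized reads, and mt-Rnr2, at 16057 against 33000. It therefore does not show a rise of mitochondrial reads as a whole. A difference in sample handling between the groups cannot be told apart from genotype in this design.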

How the results depend on the processing

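Settings on sex-linked reads, on the first principal component and on 7 libraries were chosen after seeing the data. Where no cause is named, the cause was not tested. The fit of libraries with both sex-linked kinds of reads sets control 3 alone against 4 libraries, so its values rest on that 1 control, assumed to vary like the others. Genes called higher and lower numbered 0 and 2. They were 1 and 3 with a mean of at least 50, where fewer genes are tested, and 1 and 3 with array quality weights. They were 0 and 0 with quantile normalization, without the trend, with the Y-linked share and in libraries with both sex-linked kinds of reads. They were 1 and 0 without the 2 libraries lowest on the first principal component. On recovered reads DESeq2 called 236 and 376, and on 7 libraries 123 and 255 (4533 and 2129 genes had no adjusted p), of which 308 genes in all were shared. On 7 libraries edgeR called 0 and 0. Leaving out each library gave 0 to 11 higher and 0 to 23 lower, with the most without control 3, where the presence of Xist coincides with the label. TMM recentring and quantile normalization left the median log2 fold change of all genes at -0.01 and 0.00.

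Lists called higher and lower numbered 4 and 10. They were 0 and 0 with an estimated correlation and by fry. Lists called higher were 2 with the Y-linked share, 1 in libraries with both sex-linked kinds of reads, and 2 without the libraries lowest on the first principal component. Leaving out each library gave 0 to 9 lists higher and 6 to 13 lower. Of the 14 lists, the ribosomal protein, stress response, ribosome biogenesis and acute phase lists were called in the same direction in all 19 settings with the preset correlation that keep more than 1 control. The last 2 of these were lost in the fit with control 3 alone.

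Same-numbered libraries of the groups did not deviate together (correlations -0.40, -0.04 and -0.27), so the numbers were not taken as pairs. With the replicate number as a block, 0 genes were called higher, 0 lower, and 9 lists higher. URI(+/D)Hep 4 and 5 have no part in the group difference of that fit, since no control shares their numbers.

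The Uri1 log2 fold change was 0.01. It ranged from -0.13 to 0.16 when each library was left out (-0.13 without control 3, -0.0039 without URI(+/D)Hep 2, -0.037 without 3 and -0.0061 without 5). It was highest in the fit with control 3 alone, at 0.35, and 0.21 with the Y-linked share. It was -0.0035 with edgeR, and -0.0195 with edgeR and -0.0125 with DESeq2 on 7 libraries. Of 2412 comparisons over 101 other named genes, 2394 kept their direction. Against control 3 alone, the log2 fold changes that turned were Glul -0.32, Mki67 -1.05, Ccnd1 -0.12, Afp 0.66, Pola2 -0.024, Kif4 -0.79, Abcb11 -0.045, Nfil3 0.053, Dbp -0.16, Spp1 0.27 and Pax5 -0.023. When each library was left out, Mki67 ranged from -0.47 to 1.64, Kif4 from -0.069 to 2.26 and Pfdn2 from -0.36 to 0.016, all turning without control 1, and Hif1a from -0.087, without control 3, to 0.75. The others were Mki67 -0.24 with the Y-linked share, and Pfdn2 0.0125 with array weights and 0.0176 without the libraries lowest on the first principal component. Small changes may have been missed, since 25.8% of genes changed 2-fold were recovered in simulated data. That simulation varied neither the depth nor the number of controls, and its genes varied independently.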

Other observations

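The tests on ATF4 targets were chosen after the gene results were seen. Mitochondrial ribosomal RNAs stood higher in the livers labelled URI(+/D)Hep, without passing the threshold over all genes. The normalized reads of mt-Rnr1 were 7037 ± 2069 against 14956 ± 2257 and those of mt-Rnr2 16057 ± 2230 against 33000 ± 6570 (limma adjusted p = 0.108 for both). The list of mitochondrially encoded genes had a median log2 fold change of 0.12 over 9 genes (camera adjusted p = 0.108), with 4 higher and 1 lower adjusted over the list alone. It was called higher with quantile normalization (0.26, camera adjusted p = 0.00246) and with a block for the replicate number (0.12, 0.0442). Cps1, the entry enzyme of the urea cycle, stood at 1586 ± 443 against 3175 ± 422, G6pc, which releases glucose, at 88.9 ± 22.0 against 187 ± 43.1, and Cd36, a fatty acid receptor, at 449 ± 65.2 against 233 ± 38.3. The urea cycle list had a median of 0.13 (camera adjusted p = 0.504), the periportal list 0.07 (0.631), glycolysis and gluconeogenesis 0.09 (0.735), and fatty acid synthesis -0.09 (0.631).

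The remaining lists were not called by camera in the main fit with all 8 libraries. Their median log2 fold changes were 0.22 for histones (adjusted p = 0.333), -0.35 for G1 and growth factor response (0.199), -0.03 for p53 targets (0.79), 0.07 for hepatocyte transcription factors (0.504) and -0.04 for glutamine and glutamate metabolism (0.778). They were -0.05 for serine and nucleotide synthesis (0.504), -0.04 for YAP targets (0.98), 0.09 for WNT ligands and receptors (0.79), -0.01 for HIF1 targets (0.631) and -0.01 for fatty acid oxidation (0.905). They were 0.29 for bile acid genes (0.108), 0.33 for drug metabolism (0.13), 0.07 for NRF2 targets (0.986), -0.08 for chaperones (0.199) and -0.09 for nuclear-encoded oxidative phosphorylation (0.105). They were -0.06 for interferon response (0.735), 0.04 for the circadian clock (0.986), 0.13 for Kupffer cells (0.221) and 0.31 for T and NK cells (0.584). They were 0.50 for cholangiocytes (0.986), -0.41 for fetal liver genes (0.351) and -0.23 for erythroid genes (0.064). The median and the camera direction differed in sign for YAP targets, fatty acid oxidation and interferon response. Of the 31 lists without a call in the main fit, 12 were called in at least 1 other setting, with the preset correlation. Besides the cell cycle and mitochondrially encoded lists, drug metabolism was called higher in 4 settings and lower in 1, bile acid genes higher in 3, Kupffer cells higher in 2 and histones higher in 1. Erythroid genes were called lower in 6 settings, oxidative phosphorylation in 4, chaperones in 2, and serine and nucleotide synthesis and fetal liver genes in 1 each.

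Psat1, Trib3, Slc7a5 and Atf4 all had lower values in the livers labelled URI(+/D)Hep, and the first 3 are known targets of ATF4. Among 33 other known ATF4 targets and aminoacyl-tRNA synthetase genes, 26 were negative, with a median log2 fold change of -0.21 (camera, unadjusted p = 0.00316 with the preset correlation and 0.0146 with an estimated one). Of these, 16 belonged to lists already tested, among them the stress response list, and so are no independent evidence. The 17 in no list had a median of -0.19, with 13 negative (unadjusted p = 0.0137, and 0.0515 with an estimated correlation), which did not reach the bound of -0.2. A lower ATF4 response in these livers is thus a hypothesis that may hold for the larger set. It stays open for the 17 genes in no list, whose median was -0.13 with the Y-linked share and -0.12 without control 1. These 17 were measured in the same libraries that raised the hypothesis, so they are no independent evidence either.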
